A study of Homo sapiens with 2 samples.

How the data were processed

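Visium libraries of 2 fresh frozen MDA-MB-231 tumor sections, 1 per tumor, were analysed. The values are UMI counts per gene and spot, made with Space Ranger 1.3.0 per the file headers, on hg38 per the submitters' processing notes. Spots over tissue and their array rows and columns came with the counts. The matrix holds 36601 human features and no reporter transcript, so reads from mouse cells that align to human genes cannot be told apart. Images were not used here. Of 4992 array positions, those over tissue with at least 500 UMIs were kept (2536 and 2841 spots), and the tumors were summed over zones of spots, since spots of a section are not replicates. The labels place both tumors in the same group, so no contrast between tumors was tested.

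A hypoxia score was the mean z-scored log2 of 1 plus UMIs per 10000 over a list of 28 genes, of which 27 were detected in at least 5% of spots in both tumors, smoothed over adjacent spots. Zones, lists, tests and most alternatives were fixed before the data were examined. The first comparison set the top against the bottom quartile of the score (634 and 634 spots in tumor 1, 710 and 711 in tumor 2). Score genes were not tested in it and were removed from the other lists. The second set the inner against the outer tertile by steps to the tissue border, where off-tissue areas of 5 or more positions counted as border and the frame edge did not. The near against far comparison took spots with a score under the median, split them by steps to the top quartile, and matched near and far spots on the score (402 per side in tumor 1, 410 in tumor 2).

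UMI sums per tumor and zone (4 sums, 2 tumors) were fitted in edgeR 4.0.16 with TMM scaling, filterByExpr and a quasi-likelihood F test with the tumor as a block, which leaves 1 residual degree of freedom. The prior degrees of freedom of the variance were 15.4 and 15.3 in the first 2 comparisons and unbounded in the near against far one. Genes were called at a Benjamini-Hochberg adjusted p of 0.05. Log2 values per tumor used a prior count of 2. For 24 gene lists and, in the second comparison, the score list, camera of limma 3.58.1 was run with a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a comparison, and members were also adjusted over the list alone. The preset correlation is an assumption: with a correlation estimated from 1 residual degree of freedom, no list passed in any of the 3 comparisons, and none passed by the directional test of fry. The lists of other cells were markers of fibroblasts, endothelium, macrophages and granulocytes, red blood cells, skeletal muscle, adipocytes and skin epithelium. Moran I used log2 of 1 plus UMIs per 10000 over adjacent spots, for genes with a mean of at least 0.5 UMI per spot.

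Named genes followed a rule set in advance: among called genes with the same sign in both tumors and a mean of at least 20 CPM, the 12 highest and 12 lowest log2 fold changes per comparison, without score genes and genes named by a clone. Added to these were the 2 members of each list with the largest absolute log2 fold change, MUC1, and the 15 genes with the highest Moran I. List members that did not pass are mostly not printed, and 1 other gene named by this rule is not reported here. SAA1 in the near against far comparison and the genes named in the closing section were chosen after their values were seen. Positions came from a RefSeq table on GRCh38.p14, in which 519 of 535 named or listed genes were matched by symbol.

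The tests were run on simulated counts with 200 changed genes. They recovered 85%, 91% and 99% of genes changed by log2 0.5 in the 3 comparisons and 100% at log2 1, with 12, 5 and 10 false calls. The simulation draws spread as the model assumes, so it does not measure how the tests fare on real tissue. Of 200 null lists, 0, 1 and 0 had a camera p under 0.05 in simulated data. Genes were drawn independently there, so the result does not check the preset correlation.

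Alternatives fixed in advance were DESeq2 size factors, library size alone, DESeq2 1.42.0, no filterByExpr, no tumor block, at least 2000 UMIs per spot, spots thinned to 1753 UMIs, each tumor left out, spots rich in markers of other cells left out, other zone widths, borders, smoothing and matching, scores from odd or even places of the list, an estimated correlation, the fry test and Pearson residuals. Leaving out the low-UMI area, found by Otsu thresholds of 11473 and 5235 smoothed UMIs, was added after the data were seen. Score maps were also turned 99 times for the high-score and the near against far comparisons. Each tumor had its own random angle, and some maps were mirrored. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.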

Results

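Spatial transcriptomes were measured on sections of 2 tumors grown from MDA-MB-231 cells, an established human triple-negative breast cancer line. The cells carry a hypoxia fate-mapping reporter, which changes the fluorescence of a cell for good once it has met low oxygen. Tumors were taken 18 days after implantation, frozen, and cut at 10 µm onto Visium slides, on which each barcoded spot captures RNA from a small patch of tissue that can hold several cells. Both tumors belong to the same group (n = 2), and their fluorescence images were not used here, so spots were not sorted by fate. The study asks whether cells that met hypoxia keep hypoxia programs after they move into oxygenated tissue. Without the fluorescence, that question could not be tested, and 3 contrasts were made within each section: spots with a high against a low hypoxia score, deep against border tissue, and low-score spots near against far from the high-score zone.

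Tumor 1 gave 58661164 unique molecular identifiers (UMIs) over 2536 spots, with a median of 23574 UMIs and 5651.5 genes per spot. Tumor 2 gave 39736292 UMIs over 2846 spots, of which 2841 had at least 500 UMIs and were kept, with a median of 15895 UMIs and 4743 genes per spot. Across 6767 genes at 20 or more CPM (counts scaled to the size of the library), log2 CPM correlated between the tumors with a Pearson r of 0.992, across genes, which are not independent replicates. A threshold on smoothed UMIs set apart a low-UMI area in each section, and whether its spots all adjoin was not measured. It took 22.4% of spots in tumor 1 (median 4819.5 UMIs per spot) and 30.2% in tumor 2 (median 1470 UMIs per spot). Of the spots 1 or 2 steps outside it, 55.7% in tumor 1 and 74.4% in tumor 2 lay in the high-score zone defined below.

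**Figure D1:**
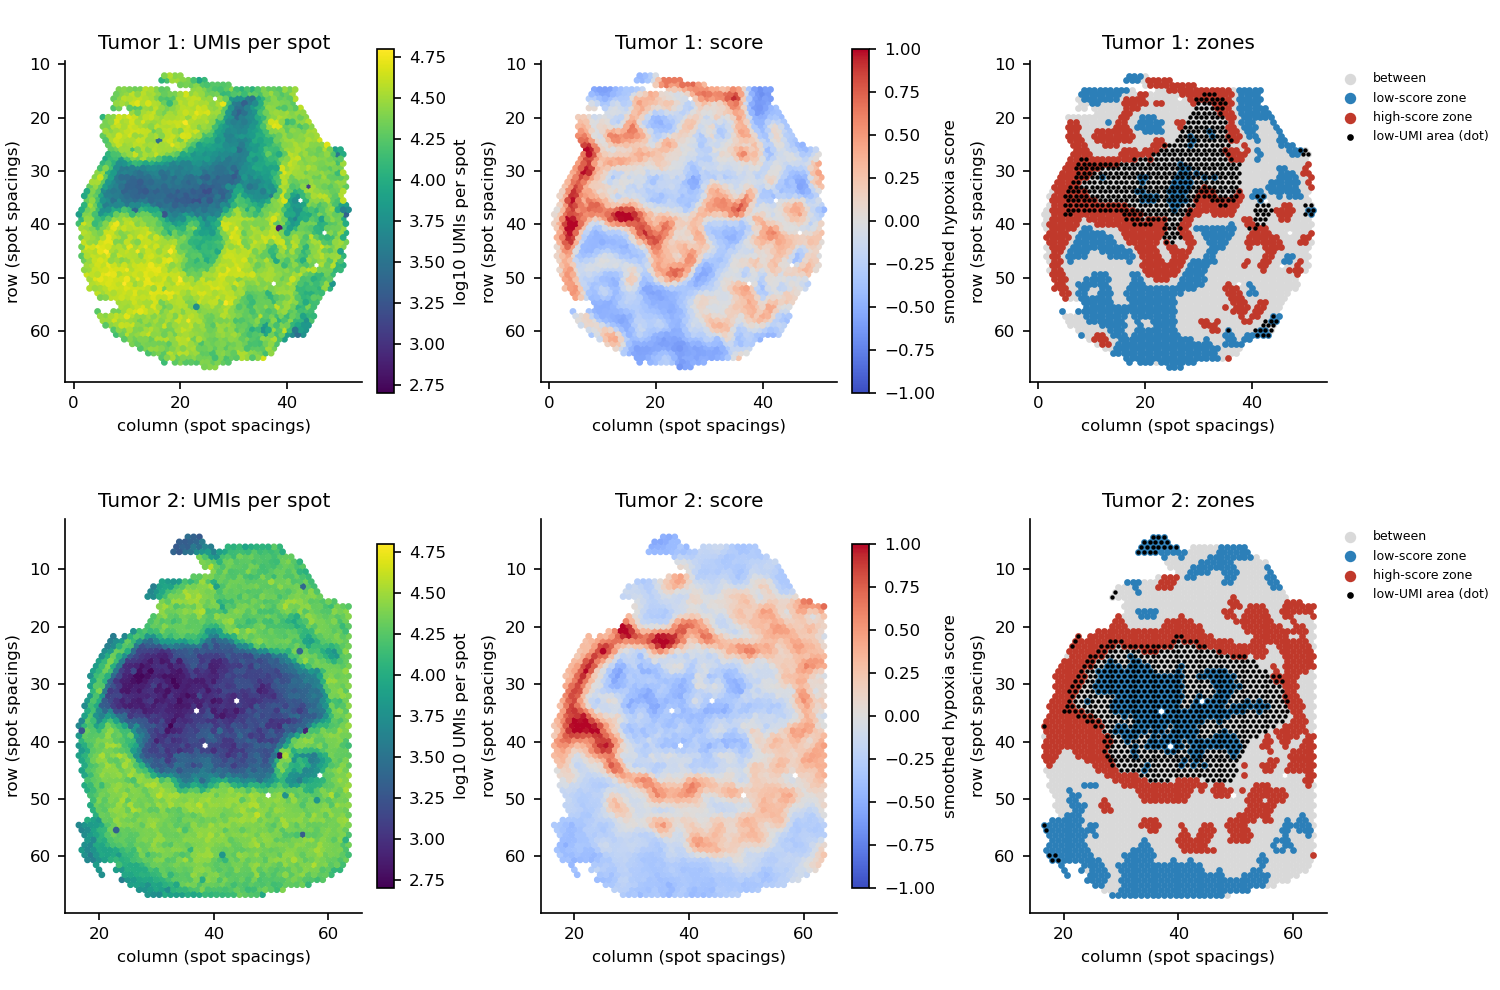
Maps of both sections, with columns and rows in spot spacings, coloured by log10 UMIs per spot (left), by the smoothed hypoxia score, which has no unit (middle), and by zone (right), where black dots mark the low-UMI area. The area takes 22.4% of spots in tumor 1 and 30.2% in tumor 2, and most spots 1 or 2 steps outside it are in the high-score zone (55.7% and 74.4%).

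Genes outside the score list also differed between the top and bottom quartile of the hypoxia score. DEPP1, a transcript induced under fasting and hypoxia (ENSG00000165507, chromosome 10, 44976128 to 44978809 in GRCh38.p14), was 10.1-fold higher than in the bottom quartile (log2 3.34 ± 0.11 SE, n = 2 tumors, edgeR adjusted p = 5.81e-12). LOX, the collagen-crosslinking lysyl oxidase (ENSG00000113083, chromosome 5, 122063195 to 122078259), was 7.64-fold higher (log2 2.93 ± 0.09 SE, n = 2, edgeR adjusted p = 2.78e-12), at 244 against 32.8 CPM in tumor 1 and 163 against 20.6 CPM in tumor 2. SLC2A3, a glucose transporter (ENSG00000059804, chromosome 12, 7919230 to 7936187), was 5.404-fold higher (log2 2.43 ± 0.09 SE, n = 2, edgeR adjusted p = 9.77e-12). The adhesion gene CDH11 (ENSG00000140937, chromosome 16, 64943753 to 65123744) had the lowest log2 fold change of the 12 genes picked as lowest (log2 -1.71 ± 0.15 SE, n = 2, edgeR adjusted p = 5.76e-07). In all, 1422 of 14156 tested genes were higher and 1172 lower in the high-score zone. Of these 2594 genes, 99.7% moved the same way in both tumors, against 71.2% of all tested genes. The calls used both tumors together, which favours genes that move alike, so the 99.7% is no independent check.

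The other named genes that rose were the heat shock gene HSPA6 (log2 3.52 ± 0.14 SE), the chemokine CCL26 (2.27 ± 0.16), HSPA1A (2.26 ± 0.14) and HSPA1B (2.14 ± 0.11). The metallothionein MT1X (2.20 ± 0.08), RASSF4 (2.16 ± 0.12) and ARRDC3 (2.10 ± 0.15) rose. So did the aldolase ALDOC (2.07 ± 0.12) and the glycoprotein hormone STC1 (1.96 ± 0.08). HSPA1A and HSPA1B are near-identical copies, and metallothionein genes resemble each other, so reads can be split between copies and their single values are uncertain. The named genes that fell were the matrix genes FBLN1 (log2 -1.19 ± 0.16 SE), FBN1 (-1.0 ± 0.14) and CCDC80 (-0.98 ± 0.20) and the chemokine CXCL14 (-1.17 ± 0.24). Also lower were the smooth muscle actins ACTG2 (-1.13 ± 0.16) and ACTA2 (-0.88 ± 0.14) and the cell cycle genes CDC25A (-1.13 ± 0.13) and SPC24 (-0.93 ± 0.14). The interferon-induced OAS2 (-0.99 ± 0.12) and MX1 (-0.85 ± 0.17) fell, as did MTRNR2L6 (-1.41 ± 0.31), a near-copy of a mitochondrial rRNA gene. Among these, MTRNR2L6 was at log2 -0.12 in tumor 1 and -2.40 in tumor 2, CXCL14 at -0.39 and -2.09, CCDC80 at -0.29 and -1.76, and MX1 at -1.28 and -0.26. MUC1, a transmembrane mucin (ENSG00000185499, chromosome 1, 155185824 to 155192915), was 1.49-fold higher (log2 0.58 ± 0.14 SE, n = 2, edgeR adjusted p = 0.0082), at 20.6 against 14.9 CPM in tumor 1 and 18.5 against 11.05 CPM in tumor 2. DESeq2, the fit without the tumor block and thinned spots did not call MUC1.

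**Figure D2:**
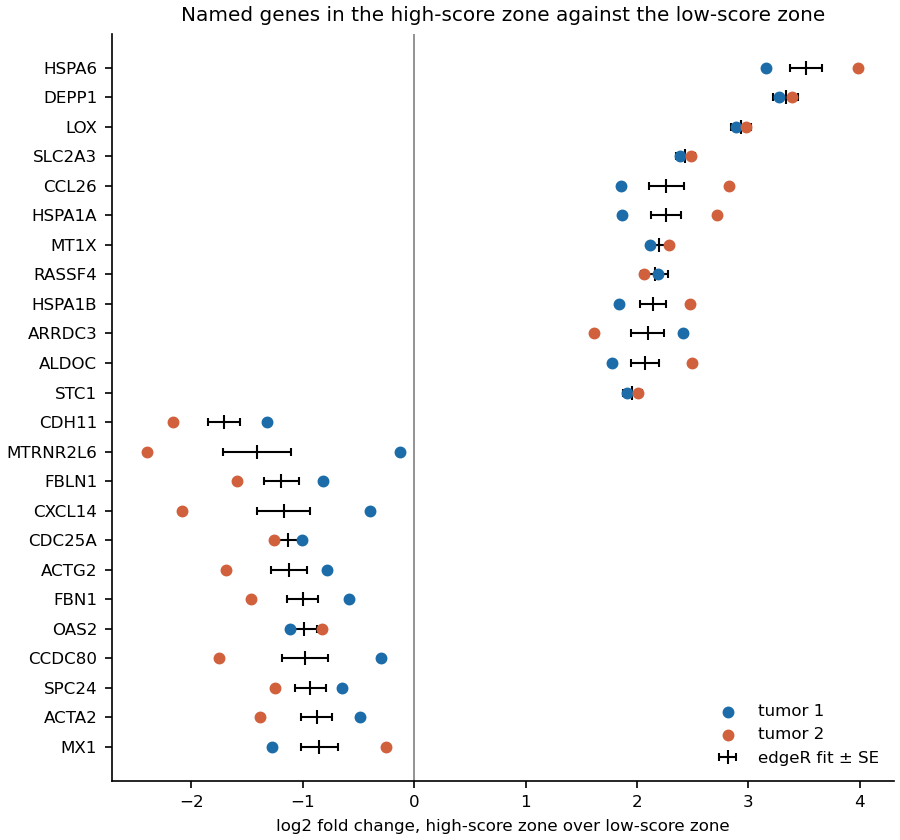
Log2 fold changes (horizontal axis) of the 24 named genes in the high-score against the low-score zone, with a dot for each of the 2 tumors and the edgeR fit ± SE as a black bar. DEPP1, LOX and SLC2A3 lie close together in both tumors, while MTRNR2L6 (-0.12 and -2.40) and CXCL14 (-0.39 and -2.09) lie apart.

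Glycolysis rose as a group: 21 of 23 members passed over all genes and 22 adjusted over the list alone, none lower, led by SLC2A3 and ALDOC (limma's camera, adjusted p = 1.22e-33; adjusted p = 0.665 with an estimated correlation). Of the heat shock genes, 6 of 12 were higher and 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 7.93e-07; adjusted p = 0.665 with an estimated correlation). Their summed level was 6793 CPM in the high-score zone and 7001 CPM at 2 steps from it in tumor 1. In tumor 2 it was 8664 and 7437 CPM. The unfolded protein and integrated stress response had 13 of 26 higher and 1 lower (14 and 1 adjusted over the list alone), led by VLDLR (log2 1.97 ± 0.15 SE) and ASNS (1.66 ± 0.52) (camera adjusted p = 1.82e-06; adjusted p = 0.665 with an estimated correlation). NF-kB and inflammatory genes had 10 of 23 higher and 1 lower (13 and 2 adjusted over the list alone), led by the prostaglandin synthase PTGS2 (log2 2.60 ± 0.18 SE), with the growth factor gene CSF3 at 1.42 ± 0.57 without passing (camera adjusted p = 8.81e-08; adjusted p = 0.665 with an estimated correlation). Immediate early genes had 11 of 20 higher and 2 lower (13 and 2 adjusted over the list alone), led by DUSP1 (1.45 ± 0.10) and FOS (1.34 ± 0.15) (camera adjusted p = 5.16e-07; adjusted p = 0.665 with an estimated correlation). Ribosomal protein genes had 23 of 31 higher and none lower (27 adjusted over the list alone), led by RPS18 (0.47 ± 0.08) and RPL18 (0.47 ± 0.08) (camera adjusted p = 2.58e-11; adjusted p = 0.665 with an estimated correlation). Oxidative stress defence was mixed, with 9 of 25 higher, including MT1X and HMOX1 (1.54 ± 0.16), and 4 lower (10 and 6 adjusted over the list alone; camera adjusted p = 0.0413; adjusted p = 0.665 with an estimated correlation).

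Replication genes were lower in the high-score zone. Of the S phase list, 25 of 26 members fell and none rose (26 adjusted over the list alone), led by CLSPN (log2 -0.73 ± 0.10 SE) and RRM2 (-0.72 ± 0.08) (camera adjusted p = 1.79e-22; adjusted p = 0.665 with an estimated correlation). Of the G2 and M phase list, 21 of 30 fell (23 adjusted over the list alone), led by KIF23 (-0.53 ± 0.09) and KIF2C (-0.52 ± 0.10) (camera adjusted p = 1.67e-12; adjusted p = 0.665 with an estimated correlation). Interferon response genes had 15 of 26 lower and 3 higher (18 and 3 adjusted over the list alone), led by OAS2 and MX1 (camera adjusted p = 3.71e-06; adjusted p = 0.665 with an estimated correlation). Fibroblast markers had 4 of 13 lower, with the same count adjusted over the list alone, led by FAP (-1.83 ± 0.34) and FBLN1 (camera adjusted p = 2.69e-04; adjusted p = 0.665 with an estimated correlation). Macrophage and granulocyte markers had 7 of 12 lower and 1 higher, with the same counts adjusted over the list alone, led by AIF1 (-1.43 ± 0.27) and C1QB (-1.24 ± 0.21) (camera adjusted p = 2.69e-04; adjusted p = 0.721 with an estimated correlation). The fibroblast list median was -0.19 in tumor 1 and -0.99 in tumor 2, and the macrophage list median -0.43 and -1.33. The share of UMIs in markers of other cells was 0.247% in the high-score and 0.23% in the low-score zone of tumor 1, and 0.216% and 0.437% in tumor 2.

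The other 12 lists were not called as groups between these zones. Of mesenchymal and invasion genes, 9 of 28 rose, led by ITGA5 (log2 1.14 ± 0.10 SE) and MMP1 (1.06 ± 0.09), and 5 fell (11 and 6 adjusted over the list alone). Of collagen assembly genes, 5 of 19 rose, led by LOX, and 4 fell, led by LOXL3 (-0.97 ± 0.23) (6 and 5 adjusted over the list alone). Cholesterol synthesis had 1 of 20 higher, INSIG1 (0.44 ± 0.09), and 5 lower (2 and 7 adjusted over the list alone). Nuclear oxidative phosphorylation had 3 of 34 lower, led by ATP5MC1 (-0.33 ± 0.08) and ATP5F1A (-0.27 ± 0.08) (3 adjusted over the list alone), and the mitochondrial genome 1 of 13 higher, MT-ND4L (0.29 ± 0.08), and 3 lower (1 and 4 adjusted over the list alone). Apoptosis and p53 targets had 4 of 19 higher, led by CASP4 (0.56 ± 0.09), and 1 lower, BTG2 (-1.11 ± 0.29) (5 and 3 adjusted over the list alone). Epithelial markers had 4 of 15 higher, led by ELF3 (2.85 ± 0.59), and 3 lower (4 and 4 adjusted over the list alone). Skin epithelium markers had 2 of 5 higher, including PERP (0.52 ± 0.08), and 1 lower, SFN (-0.62 ± 0.09) (4 and 1 adjusted over the list alone), and endothelial markers 1 of 9 lower, AQP1 (-1.08 ± 0.27) (1 adjusted over the list alone). Of 5 muscle genes tested, 4 were lower and 1 higher, the same adjusted over the list alone, but ACTA1 was at log2 0.15 in tumor 1 and -7.33 in tumor 2, and TTN at 1.06 and -7.50. The 3 red blood cell and 3 adipocyte genes tested did not pass. The median and mean of the apoptosis, endothelial and adipocyte lists differed in sign.

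The zones were drawn from expression in the same sections, so genes that vary with the score are found by construction. Each p-value and SE rests mostly on a variance shared across genes, here and for the inner against outer tertile. The prior degrees of freedom were 15.4 and 15.3, against 1 residual. A gene on which the tumors differ can thus still pass, as MTRNR2L6 did above. The spread between these 2 sections may be technical, since the labels do not say that the sections come from separate mice. As a check, the 27 score genes used were higher by a median log2 of 1.93 in tumor 1 and 1.89 in tumor 2, and score genes held out of a score made from the other members of the list also rose (13 of 14 and 14 of 14 by edgeR). The low-score zone of tumor 2 was 47.5% low-UMI area (10.4% in tumor 1). Without the low-UMI area, 1819 genes were higher and 1521 lower. Scaling by library size alone moved the median of all genes to log2 -0.12 and the counts to 803 higher and 2312 lower, and DESeq2 called 364 higher and 128 lower.

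The inner tertile of spots, those with the most steps to the tissue border, differed from the outer tertile in named heat shock, inflammatory and matrix genes. No expression value entered these zones. COL3A1, a fibrillar collagen (ENSG00000168542, chromosome 2, 188974373 to 189012746), was 6.88-fold lower in the inner tertile (log2 -2.78 ± 0.19 SE, n = 2, edgeR adjusted p = 1.14e-07), at 123 against 555 CPM in tumor 1 and 67.1 against 750 CPM in tumor 2. COL1A2 (log2 -1.77 ± 0.12 SE) and COL1A1 (-1.63 ± 0.12) were lower too. So were EFEMP2 (-2.37 ± 0.17), SAA1 (-2.09 ± 0.17), and PCOLCE (-1.66 ± 0.15). The apolipoprotein APOE (-1.64 ± 0.10), CXCL14 (-1.58 ± 0.17), CCDC80 (-1.54 ± 0.11), MTRNR2L6 (-1.40 ± 0.19) and the complement inhibitor SERPING1 (-1.40 ± 0.09) were lower. The skeletal actin ACTA1 was at log2 -4.64 ± 0.49 SE, with -0.57 in tumor 1 and -5.84 in tumor 2. Higher in the inner tertile were HSPA6 (1.64 ± 0.32), CCL26 (1.54 ± 0.26), HSPA1A (1.3 ± 0.24), HSPA1B (1.18 ± 0.17) and DHRS2 (1.04 ± 0.11). The lipid droplet gene PLIN2 (0.96 ± 0.09), MTRNR2L12 (0.92 ± 0.14), IL7R (0.87 ± 0.12), the chemokine CXCL8 (0.84 ± 0.11), DUSP1 (0.83 ± 0.08), CITED2 (0.82 ± 0.10) and MTRNR2L8 (0.81 ± 0.16) were higher as well. MUC1 was at log2 0.37 ± 0.12 SE and did not pass (n = 2, edgeR adjusted p = 0.0839).

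Of 14703 genes, 280 were higher and 456 lower in the inner tertile, and the fold changes of the tumors correlated with a Pearson r of 0.473 across genes. DESeq2 called 24 and 89, the fit without the tumor block 9 and 41, and counting the edge of the capture frame as border 687 higher of 1584 called. MTRNR2L12, MTRNR2L8, EGLN3, ALDOC, MT-ND6, MT-ATP8, FDPS and HBB, and the cholesterol and red blood cell lists, were no longer called without the low-UMI area, which took 42.2% of the inner tertile in tumor 1 and 57.7% in tumor 2.

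Markers of fibroblasts, macrophages and muscle led the lists that were lower in the inner tertile. Fibroblast markers had 9 of 14 lower (1 higher and 9 lower adjusted over the list alone; limma's camera, adjusted p = 9.33e-26; adjusted p = 0.6 with an estimated correlation). Macrophage and granulocyte markers had 9 of 13 lower, led by APOE and CSF1R (log2 -1.62 ± 0.30 SE) (10 adjusted over the list alone; camera adjusted p = 2.58e-22; adjusted p = 0.532 with an estimated correlation). Muscle genes had 8 of 10 lower, led by TTN (-6.10 ± 0.38) and TNNT3 (-5.74 ± 0.29) (9 adjusted over the list alone; camera adjusted p = 4.68e-45; adjusted p = 0.532 with an estimated correlation), with a list median of -0.36 in tumor 1 and -5.26 in tumor 2. Mesenchymal and invasion genes had 16 of 29 lower, led by SPARC (-1.34 ± 0.14) and TWIST1 (-1.07 ± 0.26), and 2 higher (20 and 2 adjusted over the list alone; camera adjusted p = 9.31e-19; adjusted p = 0.532 with an estimated correlation). Collagen assembly had 9 of 19 lower, led by LOXL3 (-1.44 ± 0.16) and COL5A2 (-1.31 ± 0.09) (13 lower and 2 higher adjusted over the list alone; camera adjusted p = 9.46e-17; adjusted p = 0.532 with an estimated correlation). S phase had 2 of 26 lower, led by MCM5 (-0.37 ± 0.08) (12 adjusted over the list alone; camera adjusted p = 1.54e-05; adjusted p = 0.761 with an estimated correlation). G2 and M phase had 1 of 30 lower, CDC20 (-0.34 ± 0.08) (1 adjusted over the list alone; camera adjusted p = 9.34e-04; adjusted p = 0.761 with an estimated correlation). The S phase median was -0.050 in tumor 1 and -0.37 in tumor 2, and that of G2 and M phase -0.015 and -0.23. Cholesterol synthesis had 1 of 20 lower, FDPS (-0.31 ± 0.08) (5 adjusted over the list alone; camera adjusted p = 0.0224; adjusted p = 0.761 with an estimated correlation).

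Heat shock genes had 6 of 12 higher in the inner tertile (7 adjusted over the list alone; camera adjusted p = 2.13e-09; adjusted p = 0.761 with an estimated correlation). NF-kB and inflammatory genes had 7 of 22 higher, led by IL6 (log2 1.04 ± 0.16 SE) (11 adjusted over the list alone; camera adjusted p = 1.14e-09; adjusted p = 0.532 with an estimated correlation). The hypoxia score list had 6 of 28 higher, led by HILPDA (0.75 ± 0.11) and EGLN3 (0.53 ± 0.12), and 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 2.49e-06; adjusted p = 0.761 with an estimated correlation), with a median of 0.032 in tumor 1 and 0.37 in tumor 2. High-score spots made up 24.97% of the inner and 27.90% of the outer tertile in tumor 1, and 20.30% and 23.86% in tumor 2. The mean score was 0.021 inner and 0.0024 outer in tumor 1, and -0.035 and -0.014 in tumor 2. The list call thus does not show that high-score spots lie deeper. Immediate early genes had 3 of 20 higher, led by NR4A1 (1.0 ± 0.16), and 1 lower (7 and 2 adjusted over the list alone; camera adjusted p = 6.48e-04; adjusted p = 0.761 with an estimated correlation). The stress response list had 3 of 26 higher, led by ATF3 (0.66 ± 0.12) and PPP1R15A (0.49 ± 0.08) (6 adjusted over the list alone; camera adjusted p = 0.0046; adjusted p = 0.761 with an estimated correlation). The stress response median was 0.0028 in tumor 1 and 0.22 in tumor 2, and that of immediate early genes 0.056 and 0.25. The mitochondrial genome had 3 of 13 higher, led by MT-ND6 (0.75 ± 0.16) and MT-ATP8 (0.71 ± 0.16) (3 adjusted over the list alone; camera adjusted p = 0.00933; adjusted p = 0.761 with an estimated correlation). Its median was 0.026 in tumor 1 and 0.22 in tumor 2, and its direction reversed without the low-UMI area. Red blood cell genes had 2 of 3 higher, including HBB (0.53 ± 0.10) (3 adjusted over the list alone; camera adjusted p = 6.29e-04; adjusted p = 0.6 with an estimated correlation). The direction of HBB reversed in thinned spots. Ribosomal genes were called as a group with no member passing (camera adjusted p = 0.0243; adjusted p = 0.842 with an estimated correlation), at medians of 0.022 and 0.11 in tumors 1 and 2. The remaining 9 lists were not called. Glycolysis had 2 of 23 higher, SLC2A3 (0.70 ± 0.13) and ALDOC (0.37 ± 0.10), and 1 lower (4 and 2 adjusted over the list alone). Nuclear oxidative phosphorylation had 1 of 34 higher, SDHD (0.29 ± 0.07) (1 adjusted over the list alone). Oxidative stress defence had 3 of 25 higher, including SOD2 (0.43 ± 0.08), and 1 lower (5 and 2 adjusted over the list alone). Interferon response had 2 of 26 higher, including OAS1 (0.50 ± 0.10) (5 higher and 1 lower adjusted over the list alone). Apoptosis had 3 of 19 higher, including BCL2L11 (0.55 ± 0.12), and 1 lower (3 and 1 adjusted over the list alone). Epithelial markers had 1 of 15 higher, KRT17 (1.02 ± 0.17), and 3 lower (2 and 4 adjusted over the list alone). Endothelial markers had 1 of 10 lower, AQP1 (-0.89 ± 0.20), and adipocyte markers 2 of 4, ADIPOQ (-2.91 ± 0.57) and FABP4 (-1.10 ± 0.29), the same adjusted over the list alone. Skin epithelium had 1 of 6 lower, SFN (-0.51 ± 0.08) (2 higher and 2 lower adjusted over the list alone). The median and mean of the glycolysis and epithelial lists differed in sign.

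**Figure D3:**
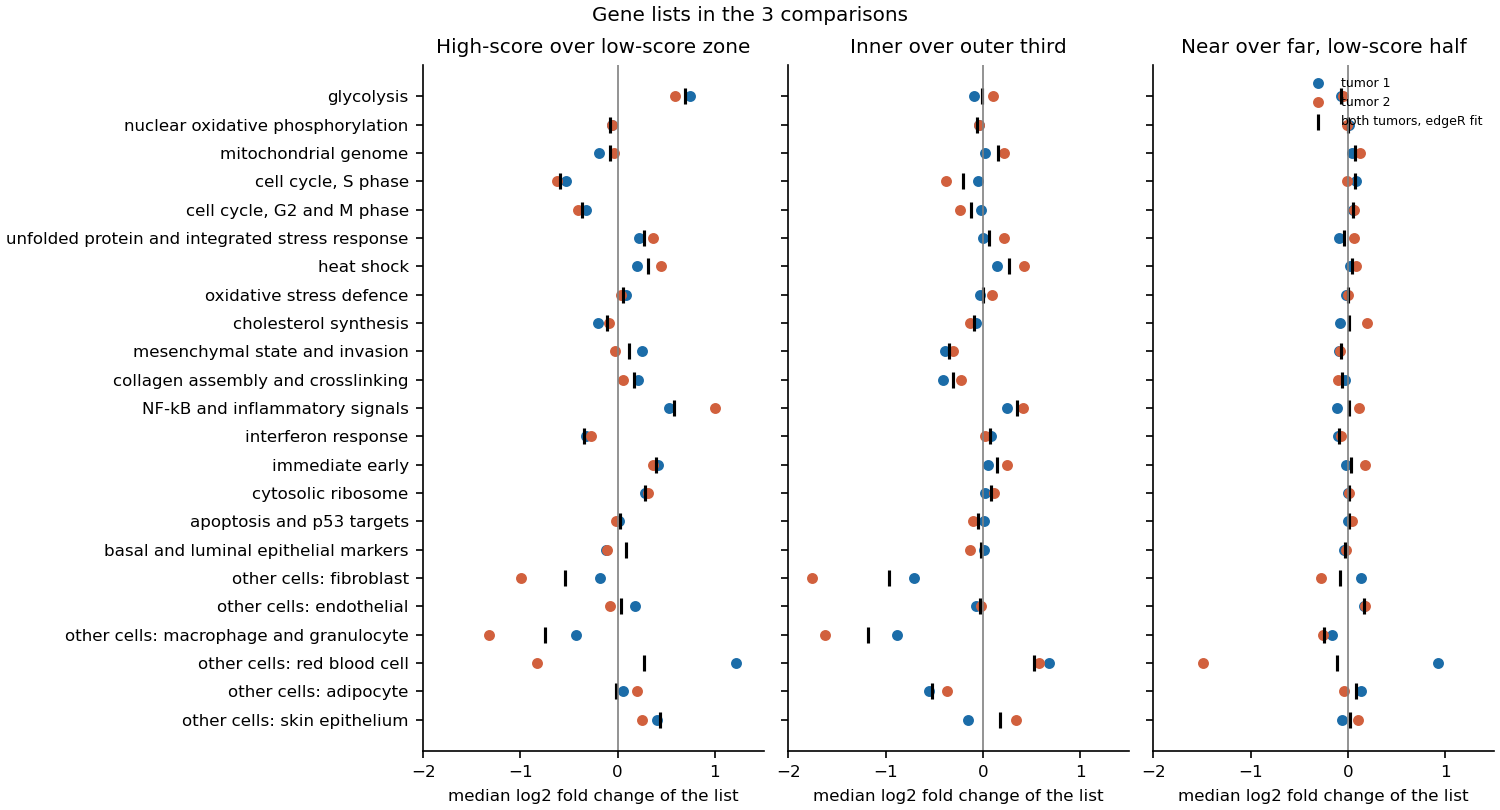
Median log2 fold change (horizontal axis) of each gene list in the 3 comparisons, with a dot for each of the 2 tumors and a black bar for the edgeR fit. The skeletal muscle list, whose tumor 2 medians lie outside the axis, and the hypoxia score list are not drawn. Glycolysis lies above 0 and S phase below 0 in both tumors in the left panel, and fibroblast markers reach -0.70 and -1.75 in the middle panel.

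The third contrast set spots near the high-score zone against spots far from it, among spots with scores below their tumor's median and at matched scores. The low scores and the matching remove any kept program that the score itself holds, so the contrast can show differences beyond the score genes alone and does not test whether hypoxia programs are kept. Of the 39 called genes, 29 moved the same way in both tumors (74.4%, against 51.7% of all tested genes), all 7 higher ones among them. Here too, calling from both tumors together favours genes that move alike. Of 13436 genes, 7 were higher near the zone and 32 lower by edgeR, and the fold changes of the tumors had a Pearson r of 0.004 across genes. DESeq2 called 0 genes, with 20 at an unadjusted p under 0.05, against 846 by edgeR. The edgeR prior on the variance had unbounded degrees of freedom here, so all genes were judged by a shared variance, and a gene on which the tumors differ can still pass. The genes higher near the zone were ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921087), a stress-induced nuclear factor (log2 0.35 ± 0.06 SE, n = 2, edgeR adjusted p = 1.55e-06), and KISS1 (0.35 ± 0.07). The histone gene HIST1H4C (0.32 ± 0.07), DUSP1 (0.29 ± 0.07), the cytokine IL11 (0.28 ± 0.06) and SNAPC1 (0.26 ± 0.06) were higher too. These SE do not measure the spread between tumors. KISS1 was at 0.12 in tumor 1 and 0.77 in tumor 2, and HIST1H4C at 0.16 and 0.63. IL11 was at 0.13 and 0.50, SNAPC1 at 0.11 and 0.48, ANKRD1 at 0.26 and 0.47, and DUSP1 at 0.26 and 0.34. The last of the 7, SAA1 (0.70 ± 0.15), lay outside the naming rule and is named after its values were seen. MUC1 was at 0.25 ± 0.15 SE and did not pass (n = 2, edgeR adjusted p = 0.866).

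Of the 32 lower genes, 9 were on the muscle list, of 10 tested, and muscle genes off the list were not counted. Adjusted over the list alone, 9 passed too (limma's camera, adjusted p = 3.99e-21, and 0.618 with an estimated correlation). The list median was 0.18 in tumor 1 and -4.24 in tumor 2. TNNT3 was at log2 0.31 in tumor 1 and -5.45 in tumor 2, and MYH1 at 0.019 and -4.79. MYLPF was lower near the zone (log2 -1.99 ± 0.12 SE), at -0.14 in tumor 1 and -3.01 in tumor 2. ENO3 (-0.68 ± 0.13) was at -0.28 in tumor 1 and -1.13 in tumor 2. Other named genes lower near the zone were CXCL14 (-0.57 ± 0.11), CST1 (-0.52 ± 0.12) and OASL (-0.43 ± 0.10). The matrix gene TNC (-0.36 ± 0.07), CCDC80 (-0.36 ± 0.08), COL6A1 (-0.31 ± 0.07), AGR2 (-0.31 ± 0.08), S100A4 (-0.29 ± 0.05), KRT19 (-0.27 ± 0.05) and TPM1 (-0.25 ± 0.06) were lower too. In thinned spots AGR2 reversed, and 16 of the called genes named for this contrast or its lists were no longer called. In the list tests, interferon response genes had 1 of 26 lower, IFI27 (-0.22 ± 0.06) (4 adjusted over the list alone; camera adjusted p = 8.07e-06), mesenchymal genes 2 of 28 lower (4 lower and 2 higher adjusted over the list alone; camera adjusted p = 4.67e-04), and collagen assembly 1 of 19 lower, COL6A1 (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.67e-04). For each of these 3 lists adjusted p = 0.618 with an estimated correlation. None of the 3 was called in thinned spots. In tumor 2 the far spots also held more transcripts of other cells (0.437% against 0.279% near), fewer UMIs (median 9650.5 against 16480.5) and lay nearer the border (median 6 against 9 steps). Glycolysis was called lower near the zone with no member passing, at a median of -0.068 (camera adjusted p = 0.00539; adjusted p = 0.618 with an estimated correlation), as were macrophage markers at -0.25 (2 lower adjusted over the list alone; camera adjusted p = 1.29e-04; adjusted p = 0.618 with an estimated correlation). Called higher with at most 1 member passing were the mitochondrial genome (median 0.077; camera adjusted p = 2.32e-04), S phase (0.076; 0.0021), G2 and M phase (0.057; 4.67e-04), heat shock (0.038; 0.0461), immediate early genes (0.034; 0.0461) and endothelial markers (0.16; 0.0211). With an estimated correlation these adjusted p-values by camera were 0.618, 0.663, 0.618, 0.867, 0.618 and 0.618. The mitochondrial genome was at 0.043 in tumor 1 and 0.12 in tumor 2, S phase at 0.085 and -0.0091, heat shock at 0.019 and 0.088, and immediate early genes at -0.015 and 0.17. The endothelial direction reversed in the lowest tertile of the score, and that of glycolysis without matching and in thinned spots. Adjusted over the list alone, 1 mitochondrial and 2 immediate early genes were higher, DUSP1 among them. The other 12 lists were not called: NF-kB had 1 of 20 higher, epithelial markers 1 of 14 lower, and the nuclear oxidative phosphorylation, stress response, oxidative stress, cholesterol, ribosome, apoptosis, fibroblast, red blood cell, adipocyte and skin lists had no member past the threshold. The median and mean of the oxidative stress, NF-kB, epithelial and red blood cell lists differed in sign. The 27 score genes, matched by design through the smoothed score, had median log2 values of -0.14 in tumor 1 and -0.11 in tumor 2. Of them, 21 and 18 were lower near the zone, so the matching did not fully equal their summed levels.

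Outside the high-score zone, score genes are lower by construction, since the zone was drawn from their smoothed levels. Their summed level was 5756 CPM inside the zone, 3237 at 1 step and 2262 at 2 steps in tumor 1, and 4926, 2783 and 2142 CPM in tumor 2. Glycolysis genes summed to 16637 CPM inside, 12293 at 2 steps and 11468 beyond 7 steps in tumor 1, and to 15037, 11896 and 11547 CPM in tumor 2. S phase genes ran the other way, from 1621 CPM inside to 2251 at 2 steps in tumor 1 and from 1717 to 2414 in tumor 2. Muscle genes were higher far from the zone in tumor 2 alone, from 138 CPM inside to 2746 CPM beyond 7 steps, against 134 and 85.4 CPM in tumor 1. MUC1 was at 19.1 CPM inside and 16.4 beyond 7 steps in tumor 1, and at 18.2 and 13.1 in tumor 2. These are values per tumor with no test.

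**Figure D4:**
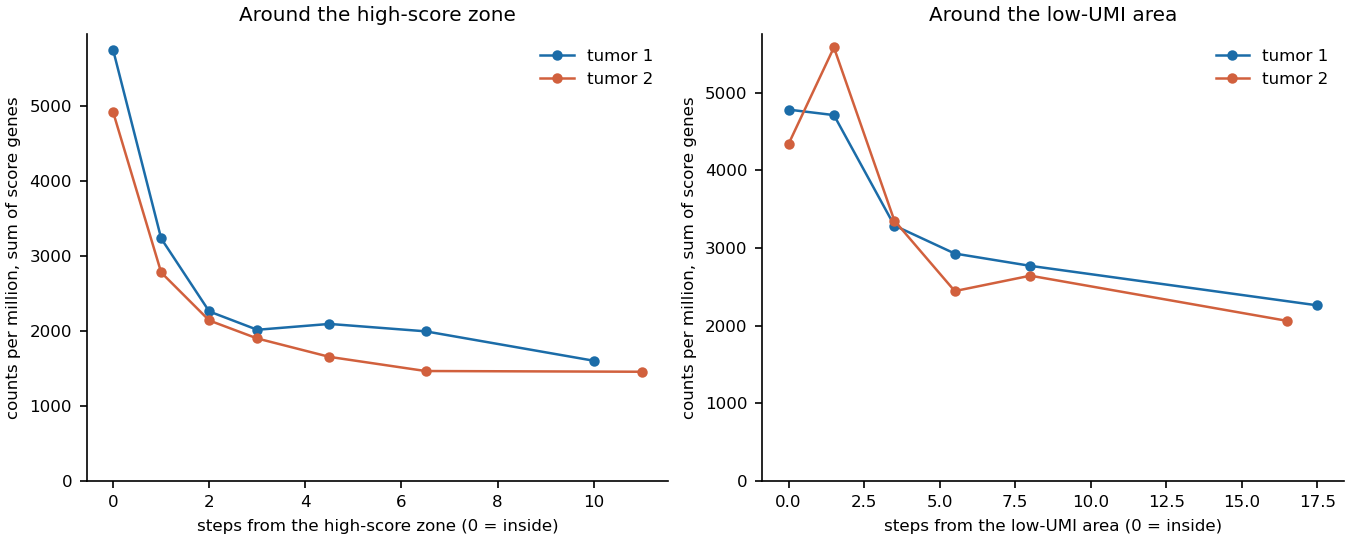
Summed CPM of the hypoxia score genes (vertical axis, from 0) against steps from the high-score zone (left) and from the low-UMI area (right), with a line for each tumor and points at the middle of each bin of steps. Levels drop from 5756 to 2262 CPM in tumor 1 and from 4926 to 2142 CPM in tumor 2 over the first 2 steps from the zone, which was drawn from these same genes.

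Some of the genes with the most patchy levels were shared by the tumors. Moran I, which is near 0 for levels without spatial pattern and near 1 for neighbouring spots alike, was taken for 4693 genes. Of the 100 highest genes of each tumor, 50 were shared, against 2.13 if every gene were equally likely to rank high. That figure ignores the level of a gene, which can affect Moran I and which agreed between the tumors (Pearson r of 0.992). The 15 highest by the lower value of the tumors were AL627171.2 (0.677), MTRNR2L12 (0.558), MT-CO2 (0.553), MT-ND3 (0.552), MT-CO1 (0.535), the calcium-binding S100A6 (0.523), COL3A1 (0.520), the elongation factor EEF1A1 (0.471), COL1A2 (0.461), COL1A1 (0.445), MT-CO3 (0.445), the score gene NDRG1 (0.444), MT-ND4 (0.433), RPS29 (0.405) and RPS27 (0.396). With Pearson residuals, 79 of the 100 highest were shared, but 12 of these 15 values moved, and AL627171.2, COL1A2, COL1A1 and RPS29 left the 15 highest.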

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

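The setting without the low-UMI area was chosen after the first results were seen, and the other settings were fixed before. Lost calls were counted over settings for the called genes named by the rule alone, where a setting tested them. They came to 49 in the high-score against low-score comparison, 123 in the inner against outer one and 115 in the near against far one. Of all 2594 genes called in the high-score comparison, DESeq2 kept 492, no tumor block 784 and thinned spots 712. Of the 736 called inner against outer, these settings kept 113, 50 and 247, and of the 39 near against far 0, 0 and 4. List calls were lost 27, 49 and 53 times. Among these, the directional test of fry and the estimated correlation each lost every called list (12, 16 and 12). In the high-score comparison, no tumor block, thinned spots and no low-UMI area lost 1 each. For inner against outer, at least 2000 UMIs lost 3, and every hole as border, no tumor block and no low-UMI area 2 each. Near the zone, the nearest and farthest tertiles lost 3 and at least 2000 UMIs 1. Leaving out spots rich in other cells or the low-UMI area lost 2 each there. In the inner against outer comparison, the frame edge as border lost 5 (mitochondrial genome, G2 and M phase, cholesterol, ribosome, red blood cell) and thinned spots 3 (G2 and M phase, stress response, cholesterol). Near the zone, thinned spots lost 7 (S phase, G2 and M phase, heat shock, mesenchymal, collagen, interferon, immediate early), and the lowest tertile of the score lost 6 of these, all but interferon. There, no tumor block lost 4 (glycolysis, mitochondrial genome, heat shock, immediate early) and no matching 4 (S phase, G2 and M phase, immediate early, endothelial). The cause of the moves below was not tested.

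High-score zone, 1422 higher and 1172 lower: DESeq2 gave 364 and 128, library size alone 803 and 2312, the fit without the tumor block 497 and 287, thinned spots 511 and 312. Inner tertile, 280 higher and 456 lower: every hole as border gave 87 and 228, DESeq2 24 and 89, the frame edge as border 687 of 1584 higher and the rest lower (9.0e2 when rounded), no tumor block 9 and 41, no filterByExpr 449 and 755, thinned spots 159 and 186. Near the zone, 7 higher and 32 lower: DESeq2 gave 0 and 0 (20 genes at an unadjusted p under 0.05), no tumor block 0 and 0 (141 genes at an unadjusted p under 0.05), at least 2000 UMIs 1 and 8, thinned spots 0 and 7. There, the lowest tertile of the score gave 3 higher, leaving out spots rich in other cells 18 lower, and the nearest and farthest tertiles 20 lower. Pearson residuals moved the shared Moran genes from 50 to 79.

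Directions reversed as follows. In the inner tertile, HBB went to log2 -0.0082 in thinned spots, and the mitochondrial genome list to -0.0085 without the low-UMI area. Near the zone, AGR2 went to 0.24 in thinned spots, and MUC1 to -0.12 in the lowest tertile, -0.88 in thinned spots and -0.098 in the nearest and farthest tertiles. The glycolysis list went to 0.029 without matching and 0.029 in thinned spots, and the endothelial list to -0.069 in the lowest tertile. With each tumor left out, ACTA1 ran from -7.33 to 0.15 and TTN from -7.50 to 1.06 in the high-score zone. Near the zone, TNNT3 ran from -5.45 to 0.31, MYH1 from -4.79 to 0.019, the muscle list from -4.24 to 0.18, the S phase list from -0.0091 to 0.085 and the immediate early list from -0.015 to 0.17.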

Other observations

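The comparison of the low-UMI area with other spots, the turned maps of the high-score comparison and both tests of the ring around the area were chosen only after results were seen. Inside the low-UMI area, mitochondrial transcripts made up more of what was left: all 13 genes of the mitochondrial genome were higher by edgeR, with a list median of log2 0.80 (camera adjusted p = 0.432 with an estimated correlation), led by MT-ATP8 (2.47 ± 0.09 SE, n = 2 tumors). MTRNR2L12 (2.92 ± 0.08), the noncoding RMRP (2.81 ± 0.18), PLCG2 (1.85 ± 0.08) and HIST1H4C (1.56 ± 0.09) were higher too, and FEN1, a replication gene, was lower (-0.81 ± 0.10). Of the score list, 22 of 28 genes were higher, with a median of 0.75 (camera adjusted p = 0.432 with an estimated correlation). In all, 694 of 15350 genes were higher and 431 lower, DESeq2 called 320, and the fold changes of the tumors had a Pearson r of 0.19 across genes.

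The genes that differ between the high-score and low-score zones could arise wherever smooth zones are laid. Of 99 turned score maps, 0 called as many (282 at most, against 2594). Each tumor was turned by its own angle, while the real zones follow the same score in both tumors. Fold changes of the tumors thus correlated at 0.134 at most in turned maps, against 0.528. The test cannot tell how many genes smooth zones matched between the tumors would give. Turning moves the zones to other tissue and does not remove the circularity of drawing zones from expression. Differences in UMIs per spot might also contribute. Thinning tests this only in part, since it left out spots under 1753 UMIs and redrew the zones. Of the 2594 called genes, 2223 were tested in thinned spots and 712 stayed called. Their log2 fold changes kept a median ratio of 1.07 over the 2223 genes (quartiles 0.76 and 1.38), so depth remains open for the shallowest spots. Leaving out the spots richest in other cells, with zones redrawn, gave a median ratio of 1.02 (quartiles 0.96 and 1.08) over 2581 called genes. Most calls thus do not rest on those spots, but the median cannot speak for the fibroblast, macrophage or matrix genes alone. For the near against far comparison, 21 of 99 turned maps called at least as many genes, so its 39 genes may be no more than smooth tissue patterns give, and no biological explanation was tested.

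Genes of fibroblasts, macrophages and muscle in the outer tertile may come from host tissue along the border, read as human genes. Fibroblast and macrophage shares rose together among outer spots, with a Spearman rho of 0.364 in tumor 1 and 0.383 in tumor 2, across spots. Human cells that switch on both programs could give the same value, and the test does not tell species apart. Muscle genes did not enter this test. For the collagen list, leaving out the spots richest in other cells left 0.674 of the median (-0.30 to -0.20), which could not tell host from tumor matrix.

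The mitochondrial share inside the low-UMI area might reflect RNA spread from spots around it, or a bias of shallow spots at any place. Against the ring around the area the genes stayed higher by log2 0.514 and 1.17, which speaks against spread. The shallowest spots outside the area showed at most 0.047 of the change, but they had a median of 12121 and 6340 UMIs against 4819.5 and 1470 inside it, so a bias of shallow spots stays open. No biological explanation was tested.

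The hypoxia score may peak in tissue around the low-UMI area, and 2 tests of this gave different answers. The mean score of the ring 1 to 4 steps outside the area exceeded the higher of inside and beyond by 0.133 and 0.327. In CPM of the score genes the ring was at 0.818 and 0.979 of the higher of inside and beyond. At 1 or 2 steps alone, levels were 4712 CPM against 4783 inside in tumor 1, and 5584 against 4341 in tumor 2, so the tumors differ by that measure. In tumor 2 the mean score inside the area was below that beyond the ring (-0.147 against -0.035), though score genes were at 4341 against 2302 CPM. In tumor 1 both were higher inside (0.048 against -0.125, and 4783 against 2577 CPM). The score and the CPM thus disagree inside the area of tumor 2, which takes 47.5% of the low-score zone there. Single spots with few UMIs may score low, which could make the ring by itself. How slowly a transcript falls off beyond the zone could be a property of the gene, but the shares left at 2 steps correlated between the tumors with a Spearman rho of only 0.116 across 71 genes, which decides nothing.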
